A study of Homo sapiens and Mus musculus with 18 samples.

How the data were processed

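Small RNA libraries were analysed from 18 samples in 3 cell lines, with 3 control and 3 targeted libraries per line. The targeted libraries are labelled ZSWIM8 knockout in K562, sgZSWIM8 in HEK293T and sgZswim8 in MEF. Per the labels' protocols, total RNA was isolated from biological triplicates with a column kit, and libraries followed a published protocol whose aim is to reduce bias in miRNA quantification. Group and replicate number were taken from the sample titles and genotype labels. K562 wild-type libraries carry the numbers 1, 2 and 3, and the knockout libraries 7, 8 and 10.

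The authors deposited 1 table of RPM (reads per 1000000 reads) per cell line, with mature miRNAs in rows. Per the submitters' processing notes, cutadapt and edgeR were used and the build was hg19; their versions and parameters, and the aligner and the miRNA annotation, were not given in the sources used here. The same notes name hg19 for the mouse samples. In the deposited K562 and MEF tables the RPM of each library summed to 1000000 within rounding, so each library was scaled to its own miRNA reads. An empty cell there was read as 0. The HEK293T table listed 611 miRNAs, 610 of them at 1 RPM or more in all 6 libraries, so miRNAs under that level in any of these libraries were not analysed here. let-7a-5p, let-7c-5p, miR-30c-5p and miR-103a-3p were among the names without a row in the tables used here. So were miR-30b-5p and the miR-23 and miR-27 members of the miR-23/27/24 clusters. miR-30b-5p and miR-30c-5p are on the list of target-directed decay substrates, so that list was not measured in full.

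Every K562 and MEF value under 3000 reads was a whole multiple of the RPM of 1 read, within 0.05 of a whole number, which gave back the whole reads of each library. Library depth was 6879095 to 15588999 miRNA reads in K562, 4023976 to 7517952 in HEK293T (from the spacing of the values) and 2877503 to 14239971 in MEF. A count of 0 then allowed up to 0.192 to 0.436 RPM in a K562 library and 0.211 to 1.043 RPM in a MEF library (3 reads). The libraries hold PCR reads, so floors and intervals from counts cover counting error only. No pair of libraries of the same group agreed within sampling noise.

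The following choices were made before the data were examined. RPM values are not counts, so the main test was limma 3.58.1 (R 4.3.3, eBayes with a mean-variance trend) on log2(RPM + 1), within each line, for miRNAs with a mean of at least 5 RPM over the 6 libraries. P-values are two-sided and Benjamini-Hochberg adjusted, with a threshold of 0.05. Fold changes are on this log2(RPM + 1) scale, which understates the change of low miRNAs. Arm ratios were log2((5p + 1)/(3p + 1)) per library for hairpins with both arms at a mean of 5 RPM or more, tested with limma without the trend. A set of 20 lists of miRNAs was tested with camera (preset correlation 0.01, and again with an estimated correlation) and with fry, for lists with at least 3 tested members. camera compares a list with the other miRNAs, and fry tests a list by itself. Counts of lists that passed, and adjusted p of lists where no test is named, are those of camera. The overlap of calls between lines was tested with a one-sided Fisher's exact test over miRNAs matched by name. Differences between lines were tested with a limma interaction term.

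The miRNAs named in the text were, per line, up to 15 called miRNAs with the largest rise and up to 8 with the largest fall among those whose control and targeted libraries did not overlap, all measured members of the lists of target-directed decay substrates and of other miRNAs reported to accumulate without ZSWIM8, miRNAs called in more than 1 line, and the opposite arm of each. Others were chosen after their values were seen, and the text says so.

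Alternatives were the pseudocounts 0.1 and 10, no filter, a minimum of 50 RPM, median-centred values, limma without the trend or with a robust prior, leaving out each library, a replicate block, and edgeR 4.0.16 (quasi-likelihood test, TMM) and DESeq2 1.42.0 on the recovered reads of K562 and MEF. edgeR and DESeq2 were not run for HEK293T, whose table lists, but for 1 miRNA, only those at 1 RPM or more in all 6 libraries.

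The fit was tested on simulated tables with 200 changed miRNAs, counting those that passed the filter. With changes drawn among miRNAs under 1000 RPM, it recovered 46.2%, 81.8% and 100% of 1.5-fold, 2-fold and 4-fold changes in K562 (13, 11 and 17 miRNAs). The shares were 41.8%, 92.0% and 100% in HEK293T (55, 50 and 48) and 3.85%, 23.5% and 85.7% in MEF (26, 17 and 21). This made 1, 4 and 0 false calls, and 1, 0 and 0 with no change at all. All miRNAs of a line were simulated with the same dispersion, from its median residual SD, and with independent libraries. No structure within groups was simulated, though the HEK293T splits given below point to some. The shares and false calls therefore hold for such simulated data, and the real fit may recover fewer changes and make more false calls. The limit of 1000 RPM was set after a first version, which drew changes from all miRNAs, had made many false calls. Over 20 draws that version made a median of 3 false calls in K562 (0 to 52), 20.5 in HEK293T (4 to 220) and 1.5 in MEF (0 to 269), against highest values of 4, 6 and 4 with the limit. Values scaled to a total thus shift the other miRNAs when abundant ones change, and no spike-in was used here to correct this.

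Guide sequences given in the labels were searched for exact matches on both strands of all 206694 GENCODE v29 transcripts (GRCh38). Introns and the mouse genome were not searched. Positions of human genes are from the same annotation. No coordinate was converted between builds.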

Results

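Small RNA sequencing measured mature miRNAs in control cells and in cells labelled as targeted at ZSWIM8, the substrate receptor of a cullin-RING ubiquitin ligase. In target-directed microRNA decay, a trigger RNA pairs extensively with a miRNA and the miRNA is then destroyed. The series asks, by its title, whether a ubiquitin ligase carries out this decay. K562 is a human erythroleukemia line, HEK293T a human embryonic kidney line, and MEFs are mouse embryonic fibroblasts. Each had 3 control and 3 targeted libraries, labelled as biological triplicates. K562 knockout cells were compared with wild-type cells, and HEK293T and MEF cells that received a guide RNA were compared with cells given a non-targeting guide (sgNT). Depth ranged from 2877503 miRNA reads in MEF sgNT library 2 to 15588999 in K562 wild-type library 1. These libraries contain no ZSWIM8 mRNA measurement, so loss of the targeted gene was not checked here.

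The guides were first compared with human transcripts. The guide in the label of the MEF sgZswim8 libraries, AGTGCGGATGAGTTTCAGCG, matched human ZSWIM8 exactly in coding exon 3 (GRCh38 chromosome 10, 73789121 to 73789140, plus strand), next to an AGG motif. The mouse gene itself was not searched. The guide in the label of the HEK293T libraries called sgZSWIM8, CATCTCAAAATGGAAGACAT, matched 0 of 23 ZSWIM8 transcripts. Its 1 exact match was in exon 4 of OIP5-AS1, the long noncoding RNA known as Cyrano that triggers miR-7 decay (chromosome 15, 41300590 to 41300609, minus strand, next to a TGG motif). The matched stretch contains GTCTTCCA, which pairs with the first 8 bases of miR-7-5p, and the same transcript holds a 13-base complement to the other end of miR-7-5p, ACAACAAAATCAC. Both sgNT guides matched 0 transcripts. For HEK293T the libraries are therefore called the libraries labelled sgZSWIM8, and any direction drawn from them carries that limit.

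miR-7-5p rose in all 3 lines. In K562 it went from 750 ± 34.0 RPM in wild-type cells to 5874 ± 1142 RPM in knockout cells (SD, n = 3 each), 7.83 times the control level. In MEF, its mouse counterpart miR-7a-5p went from 1531 ± 379 to 10919 ± 2275 RPM, 7.13 times the control level. In HEK293T it went from 5919 ± 356 to 16649 ± 2264 RPM, 2.81 times the control level. The log2 fold changes were 2.95 ± 0.16 (SE) in K562, 2.84 ± 0.29 in MEF and 1.49 ± 0.14 in HEK293T, with adjusted p = 2.6e-05, 9.8e-04 and 1.4e-04 by limma. Every targeted library lay above every control library in each line. The log2 fold change in HEK293T minus that in K562 was -1.46 ± 0.21 (limma interaction, adjusted p = 5.7e-04).

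The other arm of the miR-7 hairpin did not follow. miR-7-3p dropped by 1.03 ± 0.16 in K562 (adjusted p = 0.0089 by limma, and 0.0519 without wild-type library 2). Its log2 fold change was -0.22 ± 0.21 in HEK293T (adjusted p = 0.872), and that of miR-7a-1-3p in MEF was 0.35 ± 0.44 (adjusted p = 0.908). The ratio of 5p to 3p reads rose by 3.98 ± 0.19 in K562, 1.70 ± 0.28 in HEK293T and 2.49 ± 0.37 in MEF, with adjusted p = 5.2e-07, 0.0301 and 0.0273 by limma. The HEK293T and MEF ratio calls were lost without some single libraries, as given below. In humans, miR-7-5p is made from MIR7-1 within HNRNPK (chromosome 9, 83969748 to 83969857, minus strand), MIR7-2 (chromosome 15, 88611825 to 88611934, plus strand) and MIR7-3 (chromosome 19, 4770670 to 4770779, plus strand), all GRCh38.

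**Figure D1:**
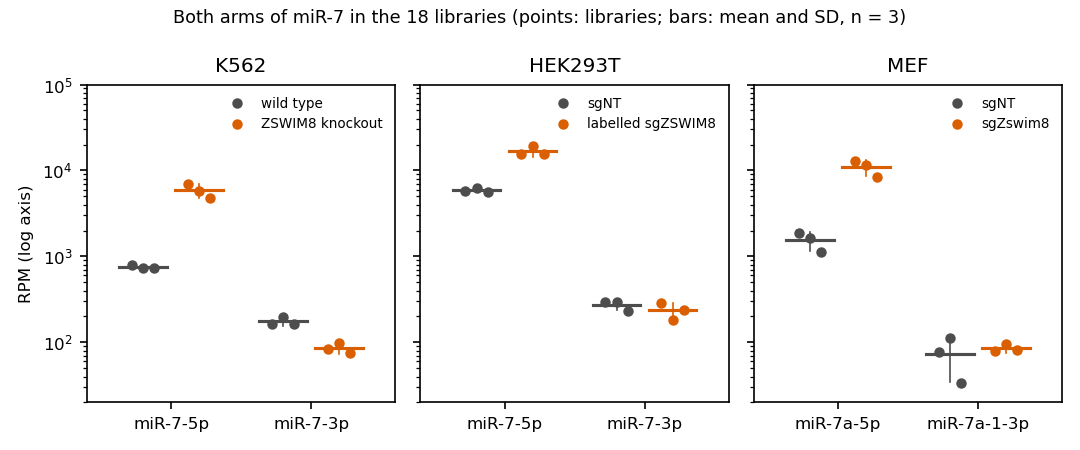
RPM on a log axis of the 5p and 3p arms of miR-7 (miR-7a in MEF) in each library of K562, HEK293T and MEF, grey for controls and orange for targeted libraries; horizontal bars are means and vertical bars SDs of 3 libraries. The 5p arm lies above its controls in every targeted library, at a mean of 5874 RPM in K562, 16649 RPM in HEK293T and 10919 RPM in MEF, while the 3p arms do not rise past the test in any of the 3 lines.

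K562 showed the most calls. Of 415 miRNAs tested, 39 rose and 24 fell, and 131 had an unadjusted p under 0.05. Any other difference between the knockout and the wild-type cells goes together with genotype. None of these calls can therefore be put down to ZSWIM8 loss alone from K562. The groups did not overlap for 39.3% of the miRNAs, where chance gives 10% for 3 against 3. Rises are ranked here among limma calls whose groups did not overlap. After miR-7-5p, the largest rises were of miR-33b-5p (1.48 ± 0.28 on the log2 scale), miR-1301-3p (1.46 ± 0.26), miR-9-3p (1.43 ± 0.32), miR-33a-5p (1.43 ± 0.25) and miR-9-5p (1.39 ± 0.35). By edgeR, miR-375-3p, chosen after its values were seen and not in this ranking, was called as higher at 3.00 (adjusted p = 0.0496). miR-33a and miR-33b are encoded within SREBF2 and SREBF1, genes for regulators of cholesterol synthesis. miR-135a-5p, miR-135b-5p, miR-450b-5p, miR-545-5p, miR-188-5p, miR-193a-3p, miR-574-3p, miR-542-3p and miR-326 rose by between 1.00 and 1.27. miR-574-5p, the opposite arm of miR-574-3p, rose by 0.88 ± 0.18, and miR-597-5p by 0.81 ± 0.16.

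The largest falls in K562 were of the clustered miR-221-3p and miR-222-3p, which target the cell cycle inhibitor p27. miR-221-3p went from 419 ± 32.3 to 10.8 ± 1.19 RPM and miR-222-3p from 325 ± 42.0 to 8.73 ± 1.38 RPM, log2 fold changes of -5.15 ± 0.15 and -5.07 ± 0.17 (adjusted p = 8.1e-07 and 1.7e-06 by limma). The 5p arms had 147 reads of miR-221-5p and 34 of miR-222-5p over the 3 wild-type libraries and 0 reads of either over the 3 knockout libraries. This made miR-221-5p at least 38.5-fold lower and miR-222-5p at least 8.90-fold lower, with a floor of 3 reads over the group. Both lie in MIR222HG on chromosome X (GRCh38, 45746157 to 45747124 for the pair, minus strand). miR-10b-5p dropped by 2.47 ± 0.52, miR-1246 by 2.02 ± 0.13, miR-944 by 1.97 ± 0.34, miR-4772-3p by 1.95 ± 0.42, miR-34a-5p, a p53 target, by 1.93 ± 0.39 and miR-4521 by 1.63 ± 0.28.

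By list, limma called in K562 1 of 4 measured substrates of target-directed decay as higher (miR-7-5p) and 2 as lower (miR-221-3p, miR-222-3p). The counts adjusted over the list alone were 2 and 2, the second rise being miR-29b-3p at 0.65 ± 0.20 (adjusted p over all miRNAs 0.0659). miR-424-5p (0.66 ± 0.19) and miR-503-5p (0.64 ± 0.20), from the list of other miRNAs reported to accumulate without ZSWIM8, missed limma's threshold over all miRNAs (adjusted p = 0.0552 and 0.0748) and passed it adjusted over the list alone, 2 of 2. For miR-29b-3p, miR-424-5p and miR-503-5p, DESeq2 on the recovered reads gave adjusted p = 0.0463, 0.0462 and 0.0424 over all miRNAs, past the threshold, and edgeR 0.152, 0.152 and 0.173. This list had fewer than 3 tested members in K562 and in HEK293T and had no camera test there. In the cluster of miR-424 and miR-503 on chromosome X, limma called 3 of 7 members as higher (edgeR 3, DESeq2 5), and 6 when adjusted over the list alone; camera gave adjusted p = 0.0290, and adjusted p = 0.783 with an estimated correlation. Without knockout library 7 or 8, 0 lists passed camera. No other list of the 16 tested passed camera. Of the neural list limma and DESeq2 called 2 of 4 as higher (miR-9-5p and miR-9-3p) and edgeR 1 (miR-9-3p). miR-9-5p had adjusted p = 0.0601 by edgeR. Of the p53-responsive list 2 of 5 fell by all 3 tools. The log2 fold change was above 0 for 3 of the 5, with a list median of 0.28 and camera adjusted p = 0.618. For the decay substrates camera gave adjusted p = 0.569, with a median of -2.21 and a mean of -1.66. By fry they had adjusted p = 2.1e-05, and the cluster of miR-424 and miR-503 had 0.0074. The miR-29 family (0.0183) and the neural list (0.0274) also passed fry, and no other list did.

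**Figure D2:**
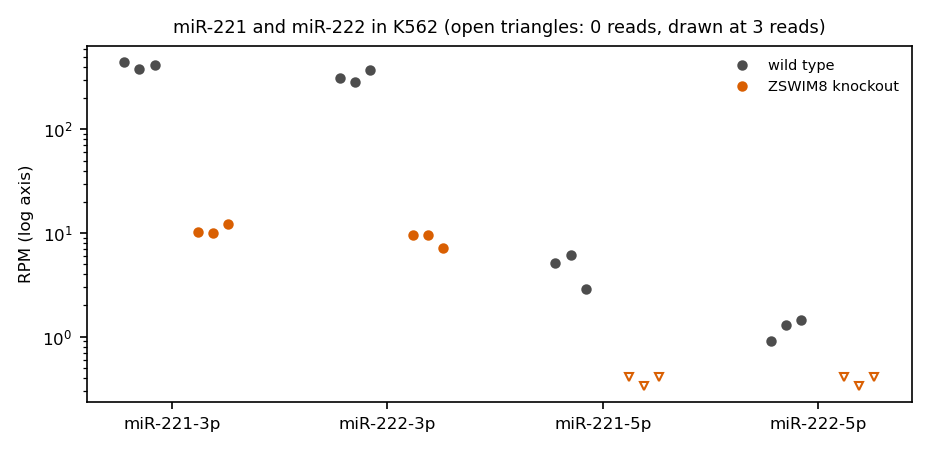
RPM on a log axis of miR-221 and miR-222 arms in each K562 library, grey for wild type and orange for knockout; open triangles mark 0 reads and are drawn at the level of 3 reads. The 3p arms average 419 and 325 RPM in wild type and 10.8 and 8.73 RPM in knockout, and the 5p arms have 0 reads in all 3 knockout libraries.

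The K562 counts moved with single libraries. Without wild-type library 1, 2 or 3 they were 13, 6 and 9 higher and 9, 6 and 7 lower, and without knockout library 7 they were 71 and 46. Median-centred values gave 25 higher and 32 lower. miR-7-5p, miR-221-3p and miR-222-3p passed the threshold in all of these settings, whereas miR-9-5p, miR-9-3p, miR-135a-5p, miR-574-3p, miR-326, miR-597-5p, miR-1301-3p, miR-10b-5p, miR-944, miR-4772-3p and miR-34a-5p each lost it without any 1 of the 3 wild-type libraries. miR-33a-5p, miR-33b-5p, miR-193a-3p, miR-574-5p and miR-4521 lost it without wild-type library 2 or 3, and miR-542-3p and miR-545-5p without wild-type library 2.

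The 5p and 3p arms of a hairpin encoded at a single locus come from the same precursor, so a change in its transcription alone leaves their ratio in place. For miR-7 and miR-29b, with several loci, and for miR-7a in MEF, where the 3p arm used was that of 1 locus (miR-7a-1-3p), a shift between loci would move the ratio too. In K562, 19 of 113 hairpins changed in arm ratio, 11 toward the 5p arm. miR-33b shifted toward 5p by 2.18 ± 0.26 and miR-33a by 1.45 ± 0.18 (adjusted p = 6.8e-04 each by limma). miR-33b-3p was at -0.70 ± 0.30 (adjusted p = 0.163) and miR-33a-3p at -0.02 ± 0.21 (adjusted p = 0.965). miR-29b shifted toward its 3p arm by 1.14 ± 0.31, written as a 5p to 3p change of -1.14 (adjusted p = 0.0384), with miR-29b-5p at -0.50 ± 0.19 (adjusted p = 0.118). Leaving out 1 library gave 6 to 46 hairpins, 6 being the lowest. In HEK293T, 1 of 138 hairpins changed (miR-7), and in MEF 2 of 120 (miR-7a and miR-335). The miR-7 ratio in HEK293T lost its call without sgNT library 1, 2 or 3 or labelled library 3, when 0 hairpins passed. Both MEF ratios lost theirs without sgNT library 1 or any 1 of the sgZswim8 libraries 1, 2 and 3, again with 0 hairpins.

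In MEF, 2 of 381 miRNAs rose and 0 fell, with 30 at an unadjusted p under 0.05. Besides miR-7a-5p, miR-335-3p rose from 37.5 ± 11.2 to 221 ± 82.4 RPM (2.50 ± 0.41, adjusted p = 0.0260 by limma). Its other arm miR-335-5p was at 0.07 ± 0.34 (adjusted p = 0.990; the sign turned with median centring), and the ratio moved toward 3p by 2.43 ± 0.41, as a 5p to 3p change of -2.43 (adjusted p = 0.0293). In humans MIR335 lies within MEST (GRCh38 chromosome 7, 130496111 to 130496204, plus strand). The miR-335-3p call was lost without sgNT library 1 (adjusted p = 0.0725) or sgZswim8 library 1 (0.150), 2 (0.236) or 3 (0.0529). edgeR's quasi-likelihood test on recovered reads called 2 higher and 0 lower, and DESeq2 8 higher and 5 lower.

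Members of the ZSWIM8 lists in MEF that missed limma's threshold over all miRNAs included miR-503-5p, 827 ± 46.9 RPM in sgNT and 2116 RPM in sgZswim8 (1.31 ± 0.30, adjusted p = 0.129), and miR-322-5p, the mouse counterpart of miR-424-5p (0.39 ± 0.37, adjusted p = 0.853). miR-503-5p was among the calls of DESeq2 (adjusted p = 0.0392) and not of edgeR (adjusted p = 0.194). Of the decay substrates 1 of 4 rose (also 1 adjusted over the list alone); camera gave adjusted p = 0.0167, and adjusted p = 0.315 with an estimated correlation. Of the other reported miRNAs 1 of 3 rose by limma (2 adjusted over the list alone; 1 by edgeR and 2 by DESeq2 over all miRNAs), with adjusted p = 0.0012 by camera and adjusted p = 0.260 with an estimated correlation. Of the cluster that holds miR-322 and miR-503 in mouse, limma and edgeR called 0 of 11 members (2 adjusted over the list alone by limma) and DESeq2 2 as higher, with a median of 0.050 and camera adjusted p = 0.521. The let-7 family (0 of 7 called by limma, edgeR or DESeq2, median 0.40) had adjusted p = 0.0167, and adjusted p = 0.680 with an estimated correlation. The Dlk1-Dio3 imprinted cluster (0 of 21 called by limma, 1 rise adjusted over the list alone, median -0.88) had camera adjusted p = 2.3e-04, and adjusted p = 0.680 with an estimated correlation. Of the 21 tested members on this list edgeR called 0 and DESeq2 called 5, in both directions. By DESeq2 miR-154-3p and miR-543-3p were higher and miR-376a-3p, miR-434-3p and miR-434-5p lower, chosen after their values were seen. The list holds miR-540-3p and not miR-540-5p. DESeq2 called miR-540-5p, chosen in the same way, as lower (-2.37, adjusted p = 0.0264), and edgeR did not (0.194). By fry, the decay substrates (adjusted p = 0.0491) and the other reported miRNAs (0.0208) passed. The let-7 family (0.234) and the Dlk1-Dio3 cluster (0.759) did not pass fry. Without sgZswim8 library 3, 0 lists passed camera. miR-221-3p and miR-222-3p were at 0.22 ± 0.20 and 0.49 ± 0.21 (adjusted p = 0.853 and 0.537), and miR-29b-3p at -0.27 ± 0.57 (0.966).

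**Figure D3:**
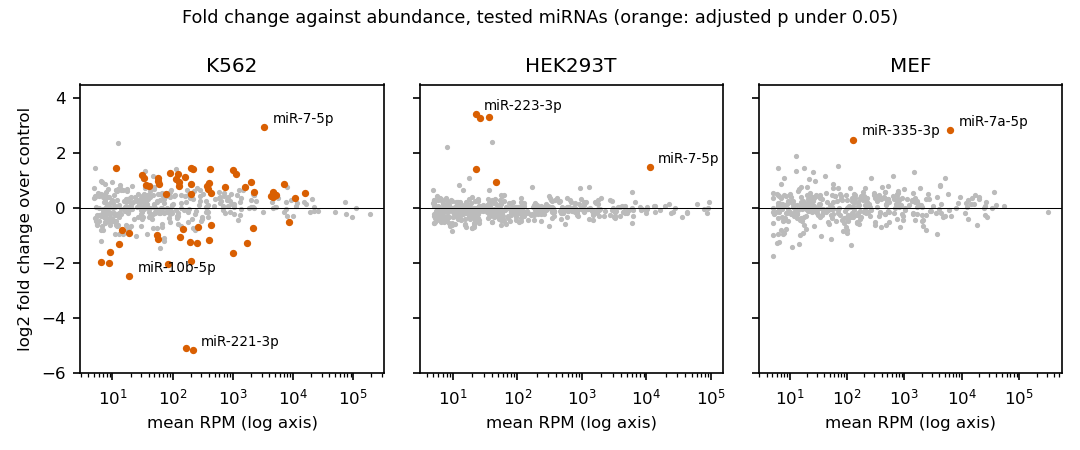
Log2 fold change of targeted over control libraries against mean RPM (log axis) for the tested miRNAs of each line; each point is a miRNA and orange marks adjusted p under 0.05. K562 has 39 orange points above 0 and 24 below, HEK293T 6 above and MEF 2 above.

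In HEK293T, 6 of 479 miRNAs rose and 0 fell in the libraries labelled sgZSWIM8, with 35 at an unadjusted p under 0.05. Besides miR-7-5p they were miR-223-3p (3.41 ± 0.55), miR-4488 (3.30 ± 0.56), miR-451a (3.29 ± 0.54), miR-1246 (1.43 ± 0.28) and miR-597-5p (0.94 ± 0.20). miR-223-3p and miR-451a are miRNAs of myeloid and red blood cells. They stood at 1.97 ± 0.44 and 2.80 ± 0.71 RPM in sgNT, and in labelled libraries 1, 2 and 3 miR-223-3p was at 11.6, 25.5 and 92.2 RPM and miR-451a at 17.2, 23.01 and 113 RPM, so the libraries of that group differed several-fold. miR-142-3p and miR-144-3p, chosen after their values were seen, had 22.99, 33.3 and 160 RPM and 4.86, 6.34 and 33.3 RPM in these libraries. miR-7-5p was at 15338, 19263 and 15345 RPM. Without the erythroid and blood cell lists, miR-1246 and miR-4488, an alternative added after the data were seen that itself took out 4 of the 6 calls, miR-7-5p was still called, and miR-597-5p, at the same log2 fold change, had adjusted p = 0.1004. The miR-597-5p call was also lost without sgNT library 1, 2 or 3 or labelled library 1 or 3, that of miR-1246 without sgNT library 2 or 3 or labelled library 3, and that of miR-4488 without sgNT library 2.

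The erythroid list (1 of 3 rose, 2 adjusted over the list alone) had adjusted p = 3.5e-04 by camera in HEK293T, and adjusted p = 0.559 with an estimated correlation. Its members, miR-451a, miR-144-3p and miR-486-5p, ranged from 0.048 to 3.29 in log2 fold change, so they did not rise alike. The let-7 family (0 of 7 called by limma, the only such test run there, median -0.42) also had adjusted p = 3.5e-04, and adjusted p = 0.559 with an estimated correlation. Of the decay substrates 1 of 4 rose (also 1 adjusted over the list alone), with adjusted p = 0.284 by camera and 0.0018 by fry. The erythroid list (0.271) and the let-7 family (0.311) did not pass fry. Of the other reported miRNAs 0 of 2 passed limma over all miRNAs and 1 adjusted over the list alone, miR-503-5p at 0.78 ± 0.21 (adjusted p = 0.164), while miR-503-3p was at -0.33 ± 0.30 (0.863). Of the cluster of miR-424 and miR-503, limma called 0 of 9 members (1 adjusted over the list alone), with a median of -0.071, a mean of 0.064 and camera adjusted p = 0.606. miR-221-3p and miR-222-3p were at -0.17 ± 0.14 and -0.32 ± 0.16 (0.855 and 0.721). With a pseudocount of 10, a minimum of 50 RPM or a robust prior the count of risen miRNAs was 1. Without sgNT library 2 it was 3, and without labelled library 2 it was 11.

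**Figure D4:**
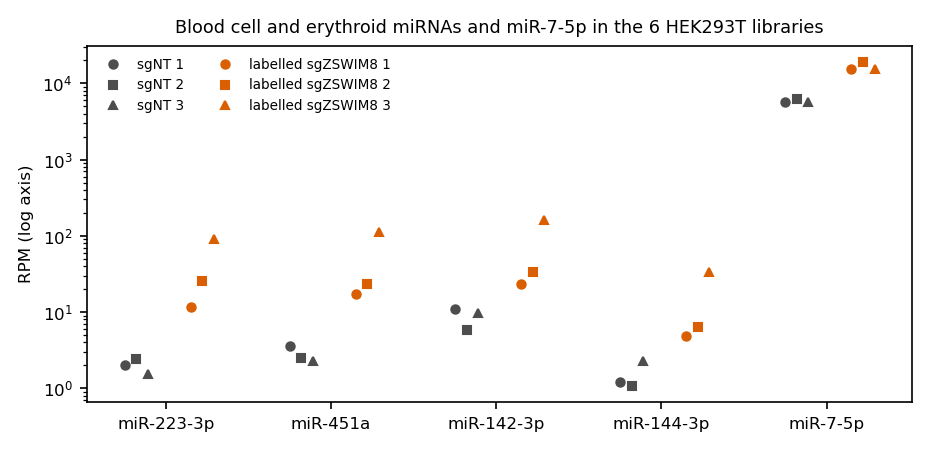
RPM on a log axis of miR-223-3p, miR-451a, miR-142-3p, miR-144-3p and miR-7-5p in the 6 HEK293T libraries, grey for sgNT and orange for the libraries labelled sgZSWIM8, with a symbol per replicate number. The first 4 miRNAs are highest in labelled library 3 (miR-451a at 113 RPM against 17.2 in library 1), and miR-7-5p lies between 15338 and 19263 RPM in the 3 labelled libraries.

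Calls were shared between lines as follows. Of 334 miRNAs tested in both K562 and HEK293T, 36 and 5 rose and 2 were shared, miR-7-5p and miR-597-5p, against 0.539 for independent lists (one-sided Fisher's exact test, p = 0.0918). Without any 1 of the K562 wild-type libraries, the HEK293T sgNT libraries or labelled libraries 1 and 3, 1 was shared, and without labelled library 2, 5 were. In the other 5 comparisons 1 or both lines had 0 calls among the shared names, so no overlap could arise and they tested nothing. Mouse miR-7a-5p does not share its name with miR-7-5p; with mouse counterparts matched, an alternative added after the data were seen, 1 rise was shared between K562 and MEF and 1 between HEK293T and MEF.

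The change of targeted against control libraries differed between K562 and HEK293T for 51 of 334 miRNAs, between K562 and MEF for 9 of 165, and between HEK293T and MEF for 3 of 193 (limma interaction, adjusted p under 0.05). K562 had wild-type controls and the other lines sgNT, and the HEK293T guide is in doubt. These differences therefore cannot be read as ones in the effect of ZSWIM8 loss alone. miR-221-3p and miR-222-3p differed most between K562 and each of the other lines by p. Leaving out 1 library gave 20 (without K562 wild-type library 2) to 58, 4 (without wild-type library 1 or 3) to 16 (without MEF sgNT library 3) and 0 to 6 differing miRNAs. The count between HEK293T and MEF was 0 without HEK293T sgNT library 1, 2 or 3, labelled library 1 or 3, MEF sgNT library 1 or sgZswim8 library 1, 2 or 3, and 6 without MEF sgNT library 2. The 3 between HEK293T and MEF were miR-92a-3p, miR-450b-5p and let-7f-5p, chosen after their values were seen.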

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

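The tests of other splits, of minor arms against miRNAs of like abundance and of differences between lines were set beforehand; the other tests given here, on miR-221 and miR-222, the HEK293T guide and the other explanations for minor arms, were chosen after the results they bear on had been seen.

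The following named miRNAs differed in their change between K562 and HEK293T by limma's interaction test with Benjamini-Hochberg adjustment, given as the log2 fold change in HEK293T minus that in K562. These lines had unlike controls and the HEK293T guide is in doubt, so the differences are not ones of ZSWIM8 loss alone. The difference was 4.98 for miR-221-3p, 4.75 for miR-222-3p, 3.45 for miR-1246, 3.06 for miR-223-3p, 2.53 for miR-451a, 2.52 for miR-34a-5p, 2.29 for miR-10b-5p and 1.34 for miR-4521. It was -1.65 for miR-1301-3p, -1.55 for miR-9-3p, -1.46 for miR-7-5p, -1.42 for miR-574-3p, -1.41 for miR-450b-5p, -1.38 for miR-9-5p, -1.37 for miR-545-5p, -1.23 for miR-574-5p, -1.14 for miR-542-3p, -0.98 for miR-135b-5p and -0.83 for miR-188-5p. miR-1246 moved in opposite directions past the test, -2.02 in K562 and 1.43 in HEK293T (adjusted p of the difference 7.1e-06). Between K562 and MEF the difference was 5.56 for miR-222-3p, 5.37 for miR-221-3p, 3.20 for miR-10b-5p, 1.77 for miR-34a-5p and -1.62 for miR-135b-5p.

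miR-221 and miR-222 were almost lost in the K562 knockout libraries. Decay of the 3p strands alone is argued against by the 5p arms: the upper 95% bound of their knockout to wild-type ratio was 0.0262 (counting error only). An effect of ZSWIM8 loss shared by every line is argued against by the lowest 95% bound of the 4 fold changes elsewhere, -0.66 in HEK293T, and by MEF alone, where the lower bounds were -0.23 and 0.02. Another difference between the knockout and the wild-type cells, such as loss of transcription of the cluster, may account for the fall: no knockout library kept more than 2.94% of the wild-type mean. It cannot be told apart from ZSWIM8 loss in K562, because all 3 knockout libraries show it and any such difference would go together with genotype.

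The guide recorded for the HEK293T libraries labelled sgZSWIM8 matched OIP5-AS1 and 0 ZSWIM8 transcripts. The label may list another guide than the one used, or the OIP5-AS1 site alone may have been altered, which would leave ZSWIM8 active. The 35 miRNAs besides miR-7-5p that rose in K562 and were also tested in HEK293T had a median of -0.05 there, with 16 above 0, and camera with an estimated correlation gave p = 0.380 (p = 0.117 with the preset one). Neither reading can be excluded, since no ZSWIM8 or OIP5-AS1 level was used here and the K562 rises may be specific to K562.

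Minor arms lay below major arms in the K562 knockout libraries: of 79 hairpins with arms at least 5-fold apart, the major arm had the higher fold change in 69, with medians of 0.28 and -0.12. A bias with abundance is argued against by miRNAs matched on mean RPM, from which minor arms differed by a median of -0.31 (95% bootstrap interval -0.51 to -0.14). An effect shared by every line was not seen in MEF, where the share was 48.9% (95% interval 38.5 to 59.5%, exact binomial). In HEK293T it was 59 of 104. Both intervals count arms or hairpins, not libraries, and single K562 wild-type libraries had shares of 44.3 to 62.0% against their own mean. MEF, where few small simulated changes were recovered, therefore does not settle whether the effect is shared. Another difference between the knockout and the wild-type cells may account for the K562 pattern and cannot be told apart from ZSWIM8 loss, as all 3 knockout libraries showed it (lowest share 81.0%).

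A split of 6 libraries into 3 and 3 can be made in 10 ways, too few for a share under 0.05. In K562 the real split called 63 miRNAs and the highest other 0, with 1 split as large. For arm ratios these values were 19, 0 and 1, and for lists 1, 4 and 7. In MEF they were 2, 0 and 1 for miRNAs, 2, 0 and 1 for arm ratios and 4, 6 and 5 for lists. In HEK293T they were 6, 15 and 2 for miRNAs, 1, 19 and 2 for arm ratios and 2, 2 and 3 for lists. The HEK293T split that put sgNT library 1 with labelled libraries 1 and 3 gave the 15 miRNAs and 19 hairpins, which points to a structure of these samples other than their groups. For differences between lines, 2 of 100 joint splits gave as many as the 51 between K562 and HEK293T (highest other 91), 3 as many as the 9 between K562 and MEF (highest other 10) and 1 as many as the 3 between HEK293T and MEF (highest other 1). These shares are under 0.05, but the set of joint splits was incomplete. Wild-type or sgNT library 1 stayed on the control side in every split, so the groups of 1 line alone were never reversed. The splits also break up the groups within each line. They therefore do not exclude chance, and say nothing of an equal effect in both lines. Leaving out 1 library took the 51 to 20 (without K562 wild-type library 2) and the 3 to 0.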

How the results depend on the processing

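The settings without blood and erythroid miRNAs, miR-1246 and miR-4488, with mouse counterparts and with libraries left out of shared calls and differences were chosen after seeing the data; causes were not tested. miR-7-5p (miR-7a-5p in MEF) and, in K562, miR-221-3p and miR-222-3p passed the test under every setting run. Other settings left 295 of 321 named values in K562, 129 of 143 in HEK293T and 142 of 148 in MEF with the same direction and side of the threshold; leaving out 1 library ended 52, 9 and 4 of their calls, added 4, 0 and 0 and turned 3, 4 and 10 signs. MEF recovered the fewest simulated changes. Its median residual SD, from which the simulated dispersion was set, was 0.453, against 0.262 in K562 and 0.254 in HEK293T. MEF also had the widest range of depth (4.94-fold), whose part was not tested.

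K562 rises numbered 20 with no filter, 25 (32 falls) with median centring, 24 without the trend, 22 (31 falls) by edgeR and 61 (42 falls) by DESeq2. At 1 RPM per arm, 8 K562 hairpins were called. HEK293T rises numbered 1 with a pseudocount of 10, a 50 RPM minimum, a robust prior or without the blood and erythroid miRNAs, miR-1246 and miR-4488, which itself removed 4 of the 6 calls. MEF rises numbered 8 and falls 5 by DESeq2. With an estimated correlation 0 lists passed in K562, HEK293T and MEF; with median centring 2 passed in MEF. With a 50 RPM minimum K562 and HEK293T shared 1 rise, and K562 and MEF differed for 3 miRNAs. With mouse counterparts matched, K562 and MEF shared 1 rise, as did HEK293T and MEF.

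Whether replicate numbers pair the libraries could not be settled from 3 libraries per group. Same-number correlations were 0.390, 0.402 and 0.00443 in HEK293T and 0.251, -0.292 and -0.0948 in MEF, and not every library correlated best with its own number. With the replicate block HEK293T had 10 rises, and MEF 1 rise (miR-335-3p had adjusted p = 0.0869 by limma) and 0 hairpins, so neither the miR-7a nor the miR-335 ratio was called. No paired analysis was possible for K562 because its groups share no number.

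Leaving out 1 library gave, in K562, 6 (without wild-type 2) to 71 rises (without knockout 7), 6 to 46 falls (the same libraries), 6 to 46 hairpins and 0 to 1 lists. In HEK293T it gave 3 (without sgNT 2) to 11 rises (without labelled 2), 0 to 0 falls, 0 to 1 hairpins and 1 to 2 lists. In MEF it gave 1 to 3 rises, 0 to 0 falls, 0 to 2 hairpins and 0 to 6 lists. K562 and HEK293T shared 1 to 5 rises and differed for 20 to 58 miRNAs, K562 and MEF for 4 to 16, and HEK293T and MEF for 0 to 6.

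Signs turned for the following, none of them called. In K562, miR-33a-3p ranged from -0.17 to 0.14 (0.10 without wild-type 2) and miR-424-3p from -0.41 to 0.16. In HEK293T, miR-424-5p ranged from -0.12 to 0.23, with -0.07 without sgNT 2 and 3 and -0.06 without labelled 3. In MEF, miR-335-5p was -0.024 with median centring and -0.026 by DESeq2, miR-322-3p -0.043 and miR-503-3p -0.0073 with median centring. Leaving out 1 MEF library gave -0.99 to 0.40 for miR-29b-3p, -0.019 to 0.68 for miR-322-5p, -0.12 to 0.72 for miR-7a-1-3p, -0.13 to 0.25 for miR-335-5p (-0.06 without sgZswim8 1), -0.61 to 0.24 for miR-221-5p, -0.32 to 0.25 for miR-322-3p (-0.14 without sgNT 3) and -0.23 to 0.45 for miR-503-3p (-0.22 without sgNT 3).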

Other observations

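The tests on miR-503 and miR-33 given here were chosen after values of these miRNAs had been seen.

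By limma over all miRNAs, the remaining lists fixed before the data were examined gave these counts. In K562, 1 of 6 members of the miR-15/16 seed family rose, as did 1 of 3 of the miR-29 family and 1 of 3 of the miR-30 family. Of the miR-23/27/24 clusters 1 of 1 rose (miR-24-3p, the only member with a row), and of the erythroid miRNAs 1 of 4 (miR-144-3p). In K562, 1 of 4 blood cell miRNAs (miR-223-5p), 1 of 3 mesenchymal miRNAs (miR-199b-5p) and 1 of 5 members of the miR-10 group (miR-10b-5p) fell. In K562 the calls in the miR-15/16, miR-29, erythroid and miR-10 lists were not made by edgeR, while DESeq2 called 2 rises, 2 rises, 1 rise, and 1 rise with 1 fall in them. In the miR-30 family edgeR and DESeq2 also called 1 rise, and DESeq2 1 fall, miR-30e-5p (adjusted p = 0.0210). miR-30e-5p, miR-24-3p, miR-144-3p, miR-223-5p and miR-199b-5p were chosen after their values were seen. In HEK293T, 1 of 2 blood cell miRNAs rose, with a median of 2.92. Of the 9 tested members of the miR-17-92 group, 0 passed limma in K562, HEK293T or MEF, with medians of 0.0028, 0.03 and 0.18. In K562, edgeR and DESeq2 each called 1 of the 9 as lower, miR-92a-3p. Of the let-7 family in K562, limma called 0 of 7, edgeR 1 as lower, and DESeq2 1 as higher and 1 as lower. The 6 mesenchymal miRNAs in MEF had a median of -0.28, with 0 called by limma, edgeR or DESeq2 (camera adjusted p = 0.0650).

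miR-503-5p lay above its controls in every targeted library of the 3 lines, though it missed limma's threshold over all miRNAs in each. DESeq2 called it in K562 and MEF (adjusted p = 0.0424 and 0.0392) and edgeR in neither (0.173 and 0.194). As a hypothesis, its mature 5p strand may accumulate in all 3 lines. An exact permutation test over the 3 lines cannot decide this: the complete separation had been seen beforehand and fixes its p at 0.00025, the smallest that 8000 permutations can give. The 5p to 3p ratio was not called by limma in HEK293T or MEF (adjusted p = 0.192 and 0.467). Averaged over both lines it was 1.17 (log2) above the controls, with exact permutation p = 0.005, the smallest that 400 permutations can give, in a test chosen after values of these lines had been seen. HEK293T carries the doubt about its guide. In K562 the 7 tested members of the miR-424 and miR-503 cluster had a median of 0.67, near miR-503-5p at 0.64, and miR-503-3p was not tested. There a rise of miR-503-5p alone cannot be told apart from one of the whole cluster. In MEF the 11 tested members of this cluster had a median of 0.050, with 6 above 0. Among them miR-450b-5p, chosen after its values were seen, was at 1.51 by DESeq2 (adjusted p = 0.0017) and 1.56 by edgeR (0.0586). miR-503-5p was at 1.25 and 1.29 by these tools, so it was not the only member called by DESeq2 or the one with the largest change.

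miR-33a and miR-33b shifted toward the 5p arm in K562, and their ratios were 0.82 ± 0.25 and 1.23 ± 0.41 in HEK293T (adjusted p = 0.456 and 0.463 over all hairpins by limma). A shift shared with mouse cells may exist, but MEF, the line in which the pattern had not been picked, does not decide. The ratio of mouse miR-33 there was 0.39 ± 0.47, with adjusted p = 0.816 over all hairpins by limma. In all, 5 tests were tried on this pattern. Those that include the lines in which it was seen gave exact permutation p = 0.005 (miR-33a) and 0.01 (miR-33b) over K562 and HEK293T and 0.00375 over 3 lines, and limma gave adjusted p = 0.0158 over the 2 hairpins in HEK293T alone. They carry little weight for that reason.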
